A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

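The measurements came from TIF-Seq, which circularises full-length cDNA and sequences the junction, so that the capped 5′ end and the polyadenylated 3′ end of the same RNA molecule are read together. The strain was FSY3636, a mating type a strain of the S288c background in which RRP6 was replaced by a drug resistance marker. RRP6 encodes a 3′ to 5′ exonuclease of the nuclear exosome. Cells grew in rich glucose medium to mid-log phase. The 4 libraries came from 2 cultures with 2 library preparations each, and they form a single group. No wild-type library is part of the series, so every level is described within the mutant and no change relative to a normal strain is given.

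The deposited table lists each distinct pair of start and end position with its strand and a read count, and the authors' count column pools the 4 libraries. The depth of each library is therefore unknown, and no SD, no n of replicates and no test across samples was possible. The planned comparisons between the 2 cultures, between the 2 library preparations, the agreement of libraries and the omission of each culture or preparation in turn were not run because the file holds 1 pooled column. Per the submitters' processing notes, CASAVA, Novoalign 2.07.10 and genome build R64 were used, and the role and settings of each are not given in the sources used here. Whether PCR copies were collapsed before counting is likewise not given in the sources used here. Reads are not independent molecules if copies remain, so all intervals and detection limits cover counting error only.

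Positions were used as deposited, 1-based on R64, together with the R64 sequence and its gene annotation. All 425462 isoforms lay within the ends of the 16 nuclear chromosomes, and 0 were mitochondrial. Each isoform was placed by the ORFs of its own strand among 6002 annotated ORFs, from start to stop codon. The classes, taken in this order, were isoforms that cover several ORFs, that cover 1 ORF, that start upstream and end inside an ORF (early end), that start inside and run past the stop codon (late start), and that lie inside an ORF. Isoforms with no ORF on their strand were placed as overlapping 1 of 411 annotated noncoding RNA genes, as antisense to an ORF or as intergenic. The last 2 classes together are called unannotated. Annotated pseudogenes were in neither gene set, so isoforms on them can fall among the unannotated ones. Levels are CPM, counts scaled to the total of all 1833796 reads, on isoforms that cover the ORF.

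Shares carry 95% Wilson intervals and CPM values exact Poisson intervals. As a one-sided limit a count of 0 allows up to 3 reads, or 1.64 CPM, where the two-sided Poisson bound is 2.01 CPM. Isoform diversity was summarised by perplexity, the exponential of the Shannon entropy of the reads over isoforms, for ORFs with at least 100 covering reads. Isoform and UTR lengths are distances on the genome and include introns. UTR lengths were taken for ORFs with at least 20 covering reads and early-end shares for ORFs with at least 50 sense reads. Divergent position means a start within 500 bases upstream of the start codon of an ORF on the other strand, and was set beside 100000 random genome positions. The median early-end share of a gene list was placed among 10000 random lists of the same size matched on reads and, as an addition after the data were seen, among lists matched on reads and ORF length. ORF length was there taken as coding bases without introns, and the smallest set of ORFs to draw from was 2 for glycolysis and for ribosomal protein genes, 4 for genes with regulatory noncoding transcription and 6 for the early termination list.

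The link between start and end was tested per ORF with at least 20 distinct isoforms by a two-sided permutation test of Spearman's correlation over distinct isoforms, with 100000 permutations and Benjamini-Hochberg adjustment at 0.05. On simulated data in which 30% of the reads were paired in order, 21.2% of 99 ORFs were recovered. With 60% paired in order, 73.0% of 100 ORFs were recovered. The 4 calls among the 1822 unlinked ORFs of that simulation were part of 98 calls in all, so they do not give the number to be found in data without links. Motif density over the first 200 bases was compared by a two-sided permutation test over distinct start sites with 100000 permutations. Start sites a few bases apart share sequence, so its p is too small, and the ratios therefore carry 95% bootstrap intervals from 2000 draws of whole 10000-base blocks of the genome. That resampling was chosen after an interval over single sites had been seen. The assignment of classes was tested on simulated data, where 1200 of 1200 isoforms received their class. The motif test called 100 of 100 simulated sets with a 1.4-fold ratio and 4 of 100 with no difference, in sets of 1000 and 1500 independent start sites, far fewer than the 36447 and 59176 sites of the real test, which are not independent.

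A polyadenylation signal means AATAAA, a variant of it with 1 changed base, or TATATA in the 50 bases before the end. Isoforms with at least 7 A among the 10 genome bases after their end were removed in an alternative, since oligo(dT) can prime there. Other alternatives were minimum reads of 2 or 5 per isoform, merging of neighbouring sites within 5 or 20 bases, ORF coverage of 90%, a tolerance of 10 bases at start and stop codon, counting of isoforms in place of reads, other windows and other gene minimums. Gene lists, tests, alternatives and the naming rule were fixed before the data were examined, apart from those named as later choices. The rule named the listed genes and, by rank, the 10 ORFs with the highest CPM, perplexity, early-end share and start to end association, and the 10 unannotated isoforms with most reads after merging of sites within 20 bases. Lists are given as sums and medians with examples, so not every listed gene is named, and 1 gene named by rank is not reported here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.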

Results

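Start and end sites of single RNA molecules were mapped in budding yeast lacking RRP6, a strain in which short noncoding transcripts escape a nuclear decay pathway. The 4 libraries, from 2 cultures with 2 preparations each, were deposited as a single pooled count. They held 1833796 reads on 425462 distinct isoforms, with 203516 start sites and 161280 end sites. Of these isoforms, 306967 (72.1%) had 1 read, while the 19803 isoforms with at least 10 reads held 66.2% of the reads. Because the libraries were pooled, no value below has a replicate error, and intervals cover counting error only.

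RRP6 itself (YOR001W, chromosome XV, 326832 to 329033, plus strand) was deleted in this strain and had 0 reads of any class on its own strand, which allows up to 1.64 CPM. On the other strand, 125 reads started within 500 bases upstream of its start codon. Mating type a genes were present, with the a-factor genes MFA1 at 1916 CPM (95% Poisson interval 1853 to 1980) and MFA2 at 979 CPM (935 to 1026), and the alpha-factor receptor gene STE2 at 81.3 CPM (68.7 to 95.4). BAR1 had 19.6 CPM, and the transporter gene STE6 had 0 covering reads and 19 reads of other classes on its strand. Genes of the other mating type reached 1.09 CPM together, from 2 reads of MF(ALPHA)1. The galactose genes summed to 8.18 CPM, of which GAL80 held 7.09 CPM, in cells grown on glucose.

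Housekeeping genes led the levels of ORF-covering isoforms. The cytosolic ribosomal protein genes held 306863 CPM (30.7% of reads), and all 137 had at least 1 read, although RPL39 and RPS20 had 3 each. The 16 glycolysis genes held 69620 CPM (6.96% of reads) and the 8 histone genes 18025 CPM. The highest level was that of TDH3 (YGR192C, chromosome VII, 882812 to 883810, minus strand), glyceraldehyde-3-phosphate dehydrogenase, at 29361 CPM (29113 to 29610), followed by the cell wall gene CCW12 at 21226, RPS3 at 20188, RPL23B at 18488 and RPS2 at 12465 CPM. GPM1, VMA3, TSA1 and RPP2A were also among the 10 highest, which held 19.1% of covering reads. Stress genes summed to 70.3 CPM, with HSP26 highest at 32.7 CPM, and the 11 meiosis genes to 3.27 CPM. Genes with known regulatory noncoding transcription held 7725 CPM, of which ADH1 had 7328, and genes known for early termination or alternative starts 188 CPM. The nuclear exosome and its cofactors summed to 882 CPM, led by the Rrp6 partner LRP1 (252 CPM, 230 to 277) and by MPP6 (169 CPM, 150 to 188), whereas the helicase gene SEN1 had 0 covering reads. Long ORFs were measured poorly: at least 1 covering read was seen for 90.2% of ORFs of 501 to 1000 bases, 27.2% of those of 3001 to 4000 bases and 1.67% of those of 4001 bases or more, so that low values of long genes such as SEN1, DIS3 and URA2 do not show low expression. The shortest ORFs, of 1 to 500 bases, were also covered less often, at 71.8%. Their median was 22 covering reads, against 54 at 501 to 1000 bases.

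Of all reads, 77.1% (Wilson interval 77.1 to 77.2) lay on isoforms that covered exactly 1 ORF. Late starts made up 10% (9.96 to 10.1), annotated noncoding RNA 5.2% (5.16 to 5.23), unannotated isoforms 5.14% (5.11 to 5.17) and early ends 1.98% (1.96 to 2.00). The unannotated part was split into 2.86% antisense and 2.29% intergenic reads. A further 0.403% lay inside ORFs and 0.133% covered several ORFs. Counted by distinct isoforms in place of reads, unannotated RNA rose to 15.1% and ORF-covering isoforms fell to 48.8%. With at least 2 and 5 reads per isoform, late starts fell to 5.68% and 4.29%, unannotated reads to 2.55% and 1.61% and early ends to 1.32% and 0.986%. ORF-covering isoforms had a median length of 899 bases (quartiles 691 and 1132), against 381 bases (279 and 547) for unannotated ones, 472 bases for early ends and 357 bases for annotated noncoding RNA.

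**Figure D1:**
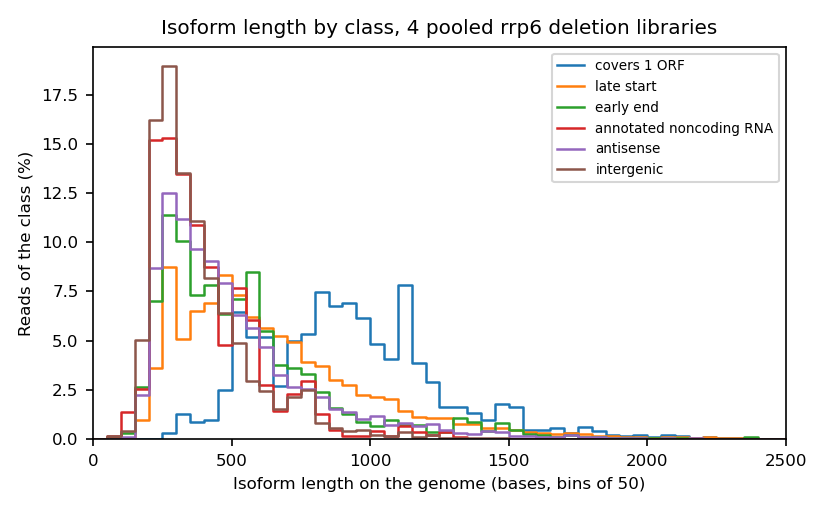
Share of reads (%) by isoform length in bins of 50 bases, for 6 classes in the 4 pooled libraries. The ORF-covering class centres on a median of 899 bases, while intergenic and antisense isoforms have medians of 332 and 431 bases.

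Well-covered genes had many distinct isoforms at exact positions. The 1213 ORFs with at least 100 covering reads had a median of 89 distinct isoforms, 26 start sites and 30 end sites, and their most used isoform held a median of 17.2% of the reads. Median perplexity was 36.8 (5th to 95th percentile 11.3 to 101). It was highest in RPL16A (278), RPL33B (253), SSS1 (234), YJL047C-A (229) and RPS17B (225), ahead of TMA19, RPL2A, CIS3, PFY1 and RPL36B. The span of YJL047C-A (chromosome X, 349044 to 349178) overlaps that of the small nucleolar RNA gene SNR60 (349130 to 349233). Isoforms that touch an ORF of their strand were counted for the ORF. The isoforms of YJL047C-A may thus be in part small nucleolar RNA molecules, which was not tested. TDH3, with far more reads, had a perplexity of 6.53 and placed 45.8% of its reads on a single isoform. Over 2388 ORFs with at least 20 covering reads, the median 5′ UTR was 39 bases and the median 3′ UTR 119 bases, both as distances on the genome that include any intron, as in RPL24A with a 5′ distance of 504 bases. The central 90% of ends spanned more bases than that of starts in 1419 ORFs, and less in 953. These counts rest on exact positions: with neighbouring sites merged within 20 bases, the median fell to 4 isoforms per ORF.

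Starts and ends of the same molecule were paired with little detectable dependence. Among 2040 ORFs tested, 3 passed the Benjamini-Hochberg threshold in the two-sided permutation test, all with upstream starts going with upstream ends. They were SFT1, which encodes a Golgi SNARE (rho = 0.387, 149 isoforms, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.0102), YJL047C-A (rho = 0.189, 498 isoforms, adjusted permutation p = 0.0102) and the ribosomal protein gene RPS14A (rho = 0.184, 596 isoforms, adjusted permutation p = 0.0136). YJL047C-A overlaps the small nucleolar RNA gene SNR60, so its link may in part be that of small nucleolar RNA molecules. The next ORF, APT2, had rho = 0.330 and an adjusted permutation p of 0.0561. RPL21A, YSY6, RPL9B, PEX19, PSF2 and PNP1 followed, with adjusted p from 0.220 to 0.605. An unadjusted permutation p under 0.05 was found in 90 ORFs (4.41%), against 3.9% of simulated ORFs without a link, and in 182 (8.92%) when the same pairs were tested against random pairing of reads. The median rho was 0.0162, against 0.00309 in the simulation without a link. The count was unstable, with 0 ORFs at a minimum of 2 reads per isoform, 369 when each read was counted, and 462 of 3378 ORFs when truncated isoforms entered. The simulated recovery of 21.2% at 30% ordered reads shows that weak links would be missed.

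Unannotated isoforms clustered upstream of genes on the other strand. Of their 94309 reads, 50.9% (50.6 to 51.2) started within 500 bases upstream of the start codon of an ORF of the other strand, against 12.2% of random positions and 17.3% of random positions outside ORFs of their strand. The share was 55.0% for antisense and 45.8% for intergenic isoforms, and 21.4% for isoforms covering an ORF. At least 1 such divergent read was found at 2741 ORFs, and at least 10 at 1006. The most were at DLD3, a lactate dehydrogenase gene, with 727, the proteasome gene RPN9 with 442, RPS28B with 430 and SLX5 with 414 reads, all 4 chosen after their counts were seen. The TRAMP poly(A) polymerase gene PAP2 had 121 divergent reads against 13 covering reads, and NAB2 had 118 against 30. Long ORFs gave few covering reads (a median of 5 at 1501 to 2000 bases, against 54 at 501 to 1000), so these counts do not compare levels.

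**Figure D2:**
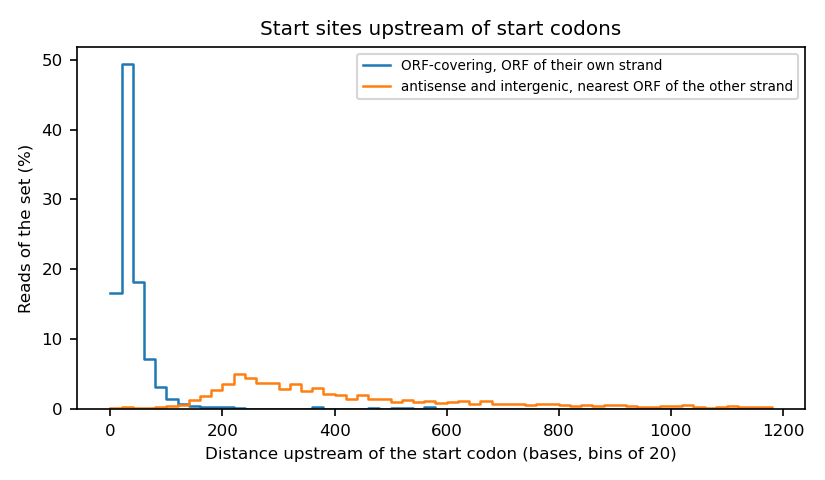
Share of reads (%) by distance of the start site upstream of a start codon in bins of 20 bases, for ORF-covering isoforms and their own ORF and for unannotated isoforms and the nearest ORF of the other strand. ORF-covering isoforms peak at 20 to 39 bases with 49.4% of their reads, whereas unannotated isoforms peak farther upstream.

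The unannotated isoform with most reads after merging lay on chromosome IV, 720788 to 721533, minus strand, with 937 reads, 485 bases from MRX16. Its end is followed by 7 A in the genome, so internal priming cannot be set aside there. Whether this isoform or the others of the 10 lie on annotated pseudogenes, which the class can hold, was not checked. The next was on chromosome V, 15638 to 15988, minus strand, with 716 reads, and its start was 367 bases upstream of DLD3 on the other strand. A transcript on chromosome XII, 855865 to 856096, had 470 reads. Another, on chromosome IV, 1321371 to 1321978, had 437 reads and ran antisense to SNX41 from a start 227 bases upstream of RPN9. On chromosome X, 172814 to 173041, 433 reads lay 447 bases from URA2, the pyrimidine synthesis gene, on the same strand. The others of the 10 had 329 to 427 reads, among them 1 on chromosome VII, 320019 to 320259, also followed by 7 A, and transcripts divergent from TMH11, SLX5 and RPS28B, the last of these antisense to the meiotic gene RED1.

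Early ends were a small share of sense reads in most genes and the larger share in a few. Long molecules were measured poorly, so these shares can overstate early ends relative to covering isoforms. In IMD2 early-ending molecules had a median length of 231 bases against 1859 for covering ones, and in HRP1 550 against 2119. Among 2355 ORFs with at least 50 sense reads the median early-end share was 0.3%, and 992 ORFs had none, but 90 ORFs exceeded 50% and 179 exceeded 20%. The 90 became 47 and 37 at minimums of 2 and 5 reads per isoform, and 146 and 15 at minimums of 20 and 200 sense reads. The list of genes known for early termination or alternative starts stood apart, with a median of 30.3% over 8 members, at percentile 99.99 of random lists matched on reads (random median 0.578%) and at percentile 99.94 of lists matched on reads and ORF length (random median 2.51%), a comparison added after the data were seen. NRD1 (YNL251C, chromosome XIV, 172588 to 174315, minus strand), which encodes an RNA-binding protein that ends noncoding transcription and limits its own mRNA, had 121 early-end and 28 covering reads (40.3% of sense reads, Wilson interval 34.9 to 46.0). HRP1 (YOL123W, chromosome XV, 87844 to 89448, plus strand), encoding a cleavage factor, had 68 and 6 (82.9%, 73.4 to 89.5). Among nucleotide synthesis genes, IMD2 (YHR216W, chromosome VIII, 554396 to 555967, plus strand) had 104 and 16 (77.6%, 69.8 to 83.8), URA8 had 34 and 4 (56.7%, 44.1 to 68.4) and ADE12 had 55 and 146 (20.3%, 15.9 to 25.5). NAB2 (10.8%, with 6 of its 8 early-end reads before A-rich genome), URA2 (4.14%) and LEU4 (2.88%) were lower, and CTH2, named TIS11 in the annotation, had 2 early-end reads among 10. Isoforms that end before the start codon do not count as early ends. For URA2 the share thus leaves out the 433 unannotated reads that lay on its strand, 447 bases from the ORF. The list median was 13.3% when each isoform needed at least 2 reads, over 5 members, 4.67% at a minimum of 5 reads, over 2 members, and 47.0% without ends before A-rich genome, over 7 members.

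The early-ending molecules of these genes differed in where they began. In URA8, ADE12, LEU4 and IMD2 they began upstream of the covering ones, by a mean difference of −130, −133, −122 and −109 bases, with adjusted p from 4.5e-05 to 0.00068 in two-sided permutation tests over distinct isoforms, exact for URA8 and LEU4. LEU4 had 4 early-ending isoforms, with starts from −465 to −167, and its median starts over reads, −208 and −170, lay closer together. In NRD1 and HRP1 the differences were 11.3 and 13.4 bases, with adjusted permutation p of 0.137 and 0.261. In NAB2, where most early-end reads lay before A-rich genome, the difference was 6.71 bases (adjusted permutation p = 0.233). SER3, a serine synthesis gene, had 153 early-end and 10 covering reads, all 153 overlapping the annotated noncoding gene SRG1, and a mean difference of −79.6 bases (adjusted permutation p = 0.0493). Both kinds had the same median start, −473, and 3 of the 9 covering isoforms, with 1 read each and starts at −335, −44 and −26, carried the difference. TIS11 had a difference of −122 bases over 2 and 4 isoforms (adjusted exact permutation p = 0.10). These 9 tests were added after the data had been seen. Many distinct isoforms share a start site, so their starts are not independent and these permutation p can be too small.

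**Figure D3:**
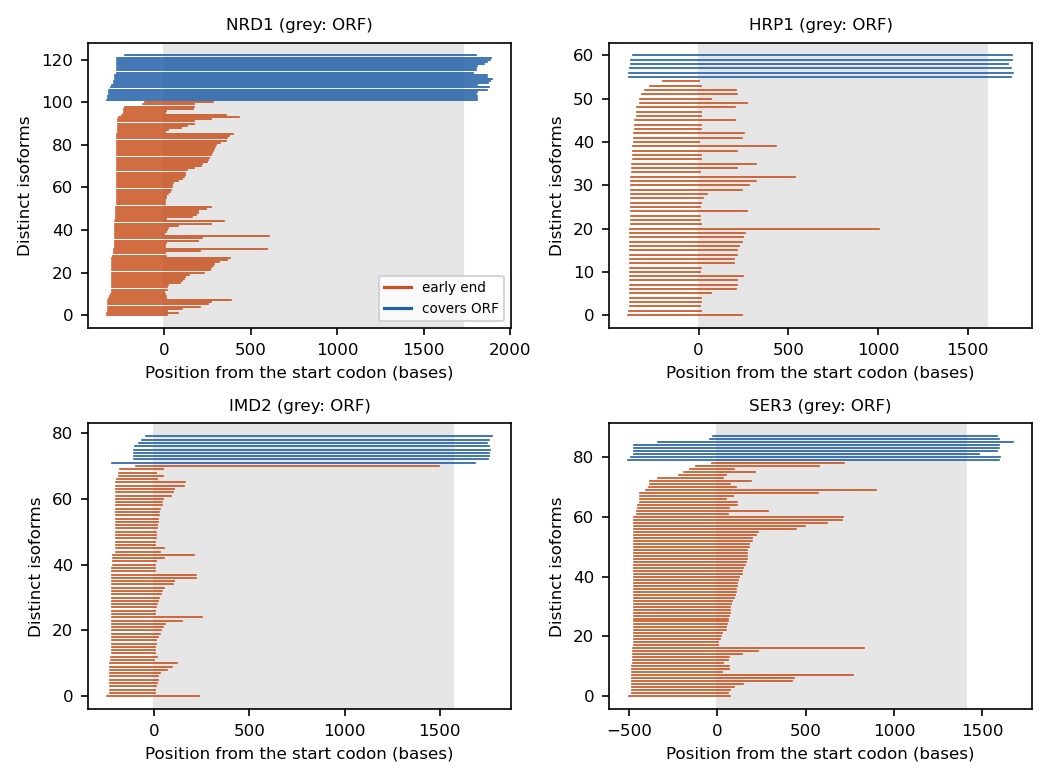
Distinct isoforms of NRD1, HRP1, IMD2 and SER3 drawn as lines from start to end, in bases from the start codon, with early ends in orange, ORF-covering isoforms in blue and the ORF in grey. In IMD2 the early-ending isoforms begin upstream of the covering ones, by a mean difference of −109 bases, while in NRD1 and HRP1 the mean differences are 11.3 and 13.4 bases.

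Among all ORFs, the highest early-end shares were those of PIR5, a cell wall protein gene with 465 of 465 sense reads ending early, and MND1, a meiotic recombination gene with 54 of 54. MEP1 (72 of 73), NNR2 (60 of 61) and ATP10 (51 of 53) were also high with starts outside other ORFs and annotated noncoding genes. The other members of the 10 had early ends that belong in part to neighbours or to A-rich sequence. In CTO1, 1277 of 1279 early-end reads overlapped the snoRNA gene SNR33, and in YLR285C-A, YLR342W-A and MTC7, 505 of 506, 178 of 184 and 272 of 275 began inside another ORF. In YDR124W, 67 of 78 ended before A-rich genome. Over all genes, 13.4% of early-end reads overlapped an annotated noncoding RNA gene. In glycolysis genes the median early-end share was 0.676%, with PGI1 at 16.3%, at percentile 99.84 of lists matched on reads. Of lists matched on reads and ORF length, 92.58% lay below it and 98.23% at or below it, so that its place there depends on ties. In histone genes it was 0.380%, with HTA2 at 7.84%, at percentiles 97.35 and 99.79. The median was 2.66% (percentile 90.99) in mating type a genes, 0.441% (percentile 64.58) in genes with regulatory noncoding transcription and 0.0361% in ribosomal protein genes (percentile 18.08, or 64.39 with ORF length matched too). Single ribosomal protein genes were far higher, with RPS14B at 46.8% (2195 early-end reads), RPS9A at 28.7% (880) and RPL7B at 24.7% (475), and the list held 5070 of the 36342 early-end reads. The exosome list had a median of 0% over 14 members, although NRD1 is a member and LRP1 had 51 early-end reads, 35 of them before A-rich genome.

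Isoforms overlapping small nucleolar RNA genes formed most of the annotated noncoding class. Small nucleolar RNAs guide modification and processing of ribosomal RNA. Their genes held 91371 reads (4.98%), with reads at 68 of 76 genes. Isoforms that also touched an ORF of their strand, as those over SNR33 in CTO1, were placed with the ORF. The totals and end positions given here leave such isoforms out, so longer extensions can be missed. SNR37 had 12023 reads, SNR30 6206, SNR82 5721, SNR33 5210 and SNR5 4816. Of reads over exactly 1 gene, 84.1% (83.9 to 84.4) started within 2 bases of the annotated 5′ end, but 98.5% (98.4 to 98.6) ended more than 10 bases past the annotated 3′ end. The assay reads polyadenylated 3′ ends, so snoRNA molecules without a poly(A) tail are not counted. These shares describe polyadenylated molecules and not all snoRNA in the cells. In all 55 genes with at least 50 reads the median end lay beyond the annotated end, by a median of 148 bases (range 14 to 597). The small nuclear RNA SNR19 (U1) had 890 reads with a median end 48 bases past its annotated end, whereas LSR1 (U2) had 301 reads with a median end at −37 bases.

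**Figure D4:**
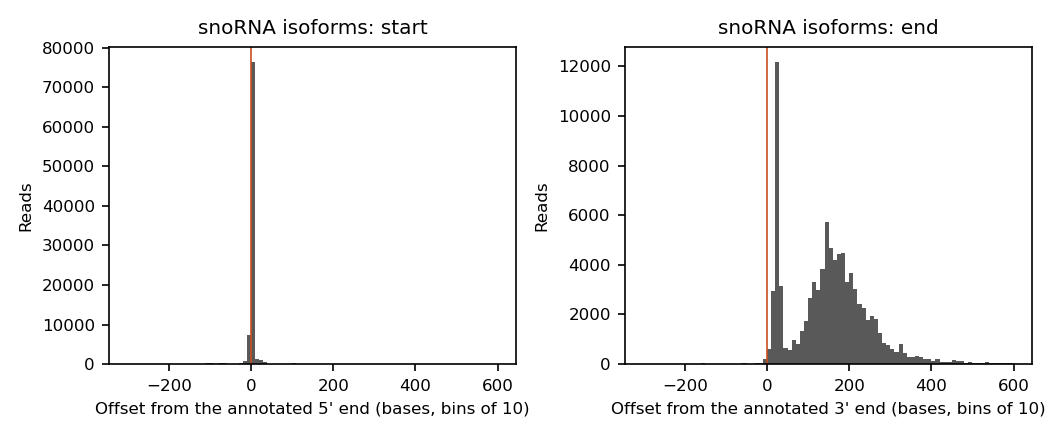
Reads of snoRNA isoforms by offset of their start from the annotated 5′ end and of their end from the annotated 3′ end, in bins of 10 bases, with 0 marked by a line. Starts pile up at the annotated 5′ end, and ends lie past the annotated 3′ end with a median of 153 bases over reads.

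The sequence at the sites separated the classes. A pyrimidine preceded a purine, the usual pattern of RNA polymerase II starts, at 60.7% (60.3 to 61.1) of start sites of ORF-covering isoforms, 70.0% (69.5 to 70.4) of unannotated ones and 71.7% (70.8 to 72.5) of early-ending ones. Counted by reads, the order of the first 2 classes turned, with 86.9% for ORF-covering and 80.9% for unannotated isoforms. A pyrimidine preceded a purine at 23.4% of random positions and at 21.5% (21.2 to 21.7) of late starts. A polyadenylation signal preceded 70.6% (70.2 to 70.9) of the ends of ORF-covering isoforms and 71.4% of late-start ends, against 45.3% (44.8 to 45.7) for unannotated isoforms, 47.1% for early ends, 40.1% for annotated noncoding RNA and 40.3% for random positions. Motifs of the termination factors were denser near starts of unannotated isoforms. The Nrd1 words GTAG or GTAA occurred 8.86 times per kb against 6.31 in ORF-covering isoforms (ratio 1.4, bootstrap interval 1.34 to 1.46), and the Nab3 words TCTT or CTTG 16.9 against 7.60 times (ratio 2.23, 2.14 to 2.32). Both comparisons gave a permutation p of 1e-05, the smallest the permutations can give. Between intergenic isoforms and the parts of ORF-covering isoforms before the start codon, which leaves out coding sequence, the Nab3 ratio was 1.45 (1.36 to 1.55), with no permutation test. Other orders of the letters were not counted for the Nab3 words, so base composition stays open as a cause of both Nab3 ratios.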

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

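The alternatives on starts inside other ORFs, on annotated noncoding RNA overlaps, on random pairing of reads and on ORF length were chosen after the data were seen. Of 135 alternative values, 94 moved, past the 95% interval of a share, level or median by 5 points for the early termination median or by more than 1.5 times for a count of ORFs or isoforms. These values are counts, shares, levels, medians, percentiles and ratios, which cannot change sign. Counting each read turned the order of pyrimidine-purine starts between ORF-covering and unannotated isoforms. Matching random lists on ORF length too lowered the percentile of the early-end share in glycolysis genes to 92.58 (98.23 with ties) and raised that of histone genes from 97.35 to 99.79, past the upper limit of the random lists. The GTAG or GTAA ratio stayed between 1.42 and 1.53 and the TCTT or CTTG ratio between 1.90 and 2.70 under all 5 alternatives each. ORFs with an early-end share above 50% numbered 84 without starts inside other ORFs, 80 without overlaps of noncoding RNA genes and 65 without A-rich ends. With at least 2 and 5 reads per isoform, distinct isoforms fell to 118495 and 37294, isoforms per ORF to 40 and 18, and ORFs with early-end shares above 50% to 47 and 37. ORF-covering reads then rose to 84.4% and 87.1%, unannotated reads fell to 2.55% and 1.61%, and divergent shares were 51.8% and 51.7%. Their median lengths were 893 and 889 bases for ORF-covering and 370 and 368 for unannotated isoforms, and 3′ UTRs were 108 and 106 bases, against 110 over all reads. Ribosomal protein genes held 354005 and 382393 CPM, glycolysis genes 82583 and 93235 CPM, the early termination list had a median of 13.3% and 4.67%, and 0 and 0 ORFs had associated starts and ends (25 and 8 at an unadjusted permutation p under 0.05). Pyrimidine-purine starts were 70.2% and 75.9% in ORF-covering and 80.1% and 82.6% in unannotated isoforms, and signals before the end 73.3% and 76.8%, and 46.9% and 52.9%. Without A-rich ends, ORF-covering reads were 76.7%, unannotated reads 5.31%, ORF-covering length 902 bases, 3′ UTRs 109 bases and the divergent share 51.8%. Ribosomal protein genes then held 299838 CPM, glycolysis genes 74805 CPM, the early termination median was 47.0%, pyrimidine-purine starts of ORF-covering isoforms 61.4%, and signals 70.1% and 44.4%. Counting each isoform once gave 48.8% ORF-covering and 15.1% unannotated, lengths of 939 and 385 bases, 5′ UTRs of 38 bases, against 31 over all reads, 3′ UTRs of 127 bases and a divergent share of 50.5%. Counting each read gave 86.9% and 80.9% pyrimidine-purine starts, 84.6% and 49.6% signals, and 369 associated ORFs. With ORF coverage of 90% and a tolerance of 10 bases, ORF-covering reads were 78.4% and 77.5%, with lengths of 898 and 898 bases. Windows of 300 and 1000 bases gave divergent shares of 28.7% and 69.2%, and minimums of 20 and 200 sense reads gave 146 and 15 ORFs with high early-end shares. Merging sites within 5 and 20 bases left 179487 and 99906 isoforms, 14 and 4 per ORF. All reads overlapping the ORF gave 325604 CPM for ribosomal protein genes and 75069 CPM for glycolysis genes. All overlapping isoforms gave 462 associated ORFs, and the real pairs tested against random pairing of reads, in place of isoforms, 5. Fewer isoforms lie behind the lower counts at higher minimums, and otherwise the cause was not tested. Omission of single libraries was not run because the 4 libraries were pooled, and reads of long ORFs were mostly late starts (82.8% at 4001 bases or more).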

Other observations

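The tests of uncapped ends at snoRNA genes, of starts inside ORFs and of GTAG and GTAA taken singly, and the resampling of genome blocks with the pooled interval, were chosen only after the result or closely related values had been seen.

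Isoforms antisense to genes were widespread, with at least 10 antisense reads at 1196 ORFs. NNR2 had 391 antisense reads beside 61 sense reads, the catalase gene CTT1 had 98 beside 14, and HTA1 had 91 beside 1609. The alpha-factor gene MF(ALPHA)2 had 0 covering reads in these mating type a cells but 39 early-ending reads. TDH1 had 20 early-ending and 10 covering reads, while TDH2 had 1 and 6719. Among other noncoding RNAs, the telomerase RNA TLC1 had 514 reads with a median end at −40 bases from its annotated end, and the RNase P RNA RPR1 had 257, both chosen after their counts were seen.

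The Nrd1 words were denser in unannotated isoforms, and against base composition, GTAG exceeded the highest of the 11 other orders of its letters by 1.25 times (bootstrap interval 1.14 to 1.37) and GTAA by 1.08 times (1.02 to 1.15), but the comparison as first written took both words together and stayed undecided. In it TAGG reached 1.34, above GTAA alone (1.26), and both words pooled exceeded TAGG by 1.05 times with an interval that includes no difference (0.969 to 1.13). The tables argue against a lack of in-frame stop codons. The ratio was 1.37 times (1.31 to 1.44) that of the other words holding TAA or TAG. The tables argue against codon use as the whole cause, but not as a part of it. Between intergenic isoforms and the parts of ORF-covering isoforms before the start codon, where neither set is translated, the ratio was 1.22 (1.15 to 1.30). It lay below the ratio of 1.4 (1.34 to 1.46) with coding sequence included, so a part played by codon use stays open. Antisense isoforms were left out as well, so the fall cannot be assigned to the coding parts. No biological explanation was tested.

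Starts at mature snoRNA 5′ ends and inside ORFs may come from uncapped ends that entered the libraries. At 12 snoRNA genes that follow another snoRNA gene within 300 bases, 97.8% of 8107 reads (97.4 to 98.1) started within 2 bases of the annotated 5′ end, as uncapped processed ends would give, although SNR61 and SNR128 held 3809 and 2844 of these reads and SNR72, with 27 reads, had 22.2%. At 48 single snoRNA genes the leading start had a pyrimidine before a purine in 47.9% (34.5 to 61.7), which lies above the 23.4% of random positions and leaves transcription starts open, and at downstream genes with at least 50 reads it did so in 1 of 7. For starts inside ORFs the share was 21.5%, near random, as cleaved or incompletely copied RNA would give, and 32.4% (30 to 34.9) at the 1403 sites with at least 10 reads, so that a part of true internal starts stays open. Transcription starts were thus tested at both kinds of site without a decision, and no other biological explanation was tested.

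Isoforms covering several ORFs held 2441 reads in 151 sets of ORFs, of which the pair YCR024C-B and PMP1, chosen after its count was seen, had 1033. Ends of different molecules could have been joined during circularisation. Pairs with an ORF of the other strand between them had 9 joined reads where the rate of direct neighbours gave 41.9, a ratio of 0.215 with a bootstrap interval of 0.0148 to 0.571. That rate was taken per product of the reads of both genes. Across direct pairs the joined reads hardly followed that product (Spearman's rho = 0.0686), so the expected value is itself uncertain. The interval reaches past the bound of 0.5 set beforehand, so joined molecules and shared transcripts cannot be told apart by it, and no biological explanation was tested.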
